A study of Mus musculus with 9 samples.

How the data were processed

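The samples are 9 sequencing libraries of sgRNA inserts amplified from genomic DNA of CT26 cells, 3 each from 2D culture, tumours of BALB/c nude mice and tumours of wild-type BALB/c mice. Per the labels, cells were selected for 7 days, mice were killed on day 11 after implantation, and inserts were read out by PCR in 2 steps. The source label describes all 9 libraries as subcutaneous tumour, and the titles and the design text set the culture libraries apart. The authors deposited a table of counts, whole numbers of reads per sgRNA and library with no normalization, as the values show. MAGeCK, a tool for pooled CRISPR screens, is named in the submitters' processing notes without a version or a role. How reads were trimmed and matched to sgRNAs is not given in the sources used here. Of the columns of sample values, 0 were left unused.

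Groups came from the library titles. All 713 gene symbols matched a gene of the GRCm38.p6 RefSeq table, 703 as the current symbol and 10 as a synonym, and symbols are printed as in the count table. No genome was used, so positions of sgRNA targets were not analysed here. Each library was counted once, as its labels list it. The chi-square per degree of freedom between culture libraries was at least 4.45, but reads copied by PCR are not independent molecules, so this value does not show that they came from separate cultures.

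The 3 pairs of groups were compared with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr by group (minimum count 10), robust dispersion and quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment at 0.05. Only the libraries of the pair entered each fit. Genes were tested on counts summed over their 4 sgRNAs, and non-targeting controls entered only the sgRNA fits. Fold changes are on the log2 scale with standard errors. Every adjusted p printed for a gene or sgRNA comes from this test unless another tool is named. TMM assumes that most sgRNAs do not change, so scaling to the non-targeting controls was an alternative.

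Before the data were examined, 20 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were pan-essential kinases, cell cycle and mitosis, transcriptional CDKs, DNA damage response, PI3K-AKT-mTOR, RAF-MEK-ERK (with MEK5 and ERK5), JNK and p38 MAPK, JAK and interferon receptor kinases, nucleic acid sensing and innate signalling, NF-kB and TNF death signalling, integrated stress response kinases, receptor tyrosine kinases, SRC and focal adhesion kinases, TGF-beta and BMP receptors, Hippo and LKB1-AMPK, autophagy and mitophagy, metabolic, casein and dual-specificity, leukocyte-restricted, and retina, muscle and germline kinases. Some genes are on several lists. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data. No list call held with the estimated correlation.

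The named genes of a comparison are, per direction, the 10 with the largest log2 fold change among those called with at least 2 sgRNAs going the same way and no overlap of the groups, filled where fewer qualified by the smallest unadjusted p and then given as values. Cdk10 with each sgRNA, up to 4 members of a list by smallest p, and 3 sgRNAs per direction were added. Not every gene or sgRNA that this rule names is printed. Lamtor3 and the genes listed where a count was 20 or fewer were named after their values were seen.

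The number of sgRNAs with at least 1 count, the Gini index, the share of counts in the top 1% of sgRNAs and the share in controls were compared by exact permutation tests of group means. The overlap of calls against the shared culture libraries was set beside 100 simulations of unchanged tumour groups. The sgRNA and gene tests were tried on simulated counts made from the real means, totals and dispersions with known 2-fold and 4-fold changes. Camera was tried on such counts with the RAF-MEK-ERK list lowered. The permutation tests, the fit of all libraries, the ratios of spread and the models with covariates were not tried on simulated counts. Over 713 genes, 100% of 2-fold changes were recovered in nude tumours against culture and 82% in immunocompetent tumours against culture, and for sgRNAs 84% and 0%. In the gene simulation many genes changed at once, all sgRNAs of a gene changed equally, and sgRNA noise was independent. The shares recovered may therefore be higher than in the real data. Alternatives were DESeq2 1.42.0 size factors or test, limma's voom with sample weights estimated per group, total count scaling, other count filters, 1 fit of all libraries, no robust step, a replicate block, leaving out each library, and for genes the mean of sgRNA log2 values, rank aggregation, fry, and leaving out the most abundant sgRNA. Leaving out libraries in the list tests was added after seeing the data.

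Totals of 2887585 to 4533348 counts gave a median of 589 to 1392.5 counts per sgRNA in a library, so counting error was small beside the spread between tumours for most sgRNAs. A count of 0 allows up to 3 counts, or 0.662 to 1.04 CPM.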

Results

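The series is a pooled CRISPR knockout screen in CT26, a mouse colon carcinoma line of BALB/c origin. Each cell carried a guide RNA (sgRNA) that directs Cas9 to a kinase or kinase-related gene, and the abundance of each sgRNA in genomic DNA was counted by sequencing. A knockout that slows growth or survival lowers the count of its sgRNAs, and one that favours growth raises it. After 7 days of selection the cells were kept in 2D culture or injected under the skin of BALB/c nude mice, which lack T cells, or of wild-type BALB/c mice, which have an intact immune system, and tumours were taken on day 11. The time at which culture cells were harvested is not given in the sources used here, so fold changes against culture include any difference in time or cell divisions. There were 3 libraries per group, 9 in all. The table holds 2952 sgRNAs, 4 for each of 713 genes and 100 non-targeting controls. Library totals ran from 3782247 to 3887727 counts in culture, from 3634360 to 4533348 in nude-mouse tumours and from 2887585 to 3667929 in immunocompetent tumours. The labels name no separate culture for the culture libraries and no mouse for each tumour, so p-values measure the spread between these libraries, part of which may be technical. Each fit used 1 dispersion per gene for both groups. The spread was unequal: with counting noise subtracted, the coefficient of variation of gene-targeting sgRNAs was 0.0872 in culture. It was 0.285 in nude-mouse and 0.607 in immunocompetent tumours. The p-values against culture therefore do not measure the spread between tumours alone.

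sgRNA counts were most even in culture and least even in immunocompetent tumours. The Gini index, which is 0 when all sgRNAs are equally abundant, was 0.309 ± 0.000940 (SD, n = 3) in culture, 0.386 ± 0.0162 in nude-mouse tumours and 0.472 ± 0.0867 in immunocompetent tumours. The top 1% of sgRNAs took 2.86% ± 0.0607 of counts in culture, 3.87% ± 0.351 in nude-mouse tumours and 6.27% ± 2.95 in immunocompetent tumours. Immunocompetent replicate 1 stood apart with 9.63% (95% Wilson interval 9.60% to 9.66%), against 4.08% and 5.11% in replicates 2 and 3. The culture libraries each held 2935 sgRNAs with at least 1 count, nude-mouse tumours 2924 ± 12.3 and immunocompetent tumours 2896 ± 22.5. The same 17 sgRNAs, 14 of them targeting a gene, had no count in any culture library, where a count of 0 allows up to 0.793 CPM (counts scaled to equal library totals). Non-targeting controls made up 4.44% ± 0.0177 of counts in culture, 4.99% ± 0.0454 in nude-mouse tumours and 5.17% ± 0.0634 in immunocompetent tumours. For the Gini index, the top 1% share and the number detected, the tumour groups did not overlap with culture (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow; Benjamini-Hochberg p = 0.133 over 12 tests) but overlapped with each other (exact p = 0.2, adjusted p = 0.2). The control share did not overlap between any pair of groups (exact p = 0.1, adjusted p = 0.133 in each comparison). The Wilson interval, the limits for a count of 0 and the intervals of count ratios given for single sgRNAs cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

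**Figure D1:**
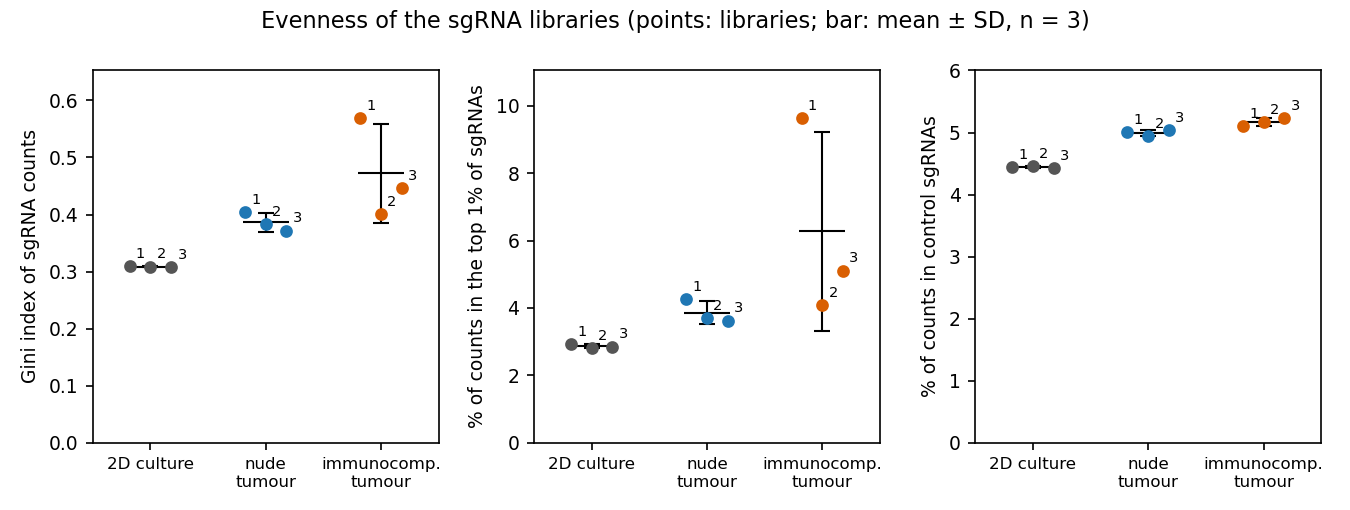
Gini index of sgRNA counts (left), percent of counts in the top 1% of sgRNAs (middle) and percent of counts in non-targeting control sgRNAs (right) for each of the 9 libraries, with the replicate number beside each point and the mean ± SD of each group as a bar. Immunocompetent replicate 1 lies highest in the left and middle panels, with 9.63% of counts in the top 1% of sgRNAs.

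The comparison of immunocompetent with nude-mouse tumours asks which knockouts are lost or gained when the host has T cells. No gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, so the following are values and not calls. sgRNAs for Ret, the receptor tyrosine kinase for ligands of the GDNF family, were 1.46 ± 0.26 higher (log2 fold change ± SE, n = 3 and 3) in immunocompetent tumours, with 4 of 4 sgRNAs higher and an adjusted p of 0.185. Nme1, a nucleoside diphosphate kinase, was 0.99 ± 0.22 higher, and Riok3, an atypical kinase of the RIO family, 1.32 ± 0.34 higher. On the other side stood Jak2, which signals from cytokine receptors, at -1.19 ± 0.37, and Stk11 (LKB1, the kinase that activates AMPK) at -1.13 ± 0.30. Mark4, a microtubule affinity-regulating kinase, was at -1.04 ± 0.26, and Ern1 (IRE1, a sensor of unfolded protein in the endoplasmic reticulum) at -0.96 ± 0.28.

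The adjusted p of each of the 6 genes after Ret was 0.245, with 4 of 4 sgRNAs on the same side for all of them except Mark4, with 3. Cdk7, the kinase of TFIIH, and Trrap, a scaffold of histone acetyltransferase complexes, were 2.89 ± 0.79 and 2.94 ± 0.79 higher, sizes that depended on single libraries or sgRNAs. Over the alternatives tried Cdk7 ran from 1.16, without its most abundant sgRNA, to 3.27 (adjusted p 0.0240 to 0.961), and was at 1.62 without immunocompetent replicate 1. Trrap ran from 1.19, without immunocompetent replicate 1, to 3.39 (adjusted p 0.0626 to 0.961). The immunocompetent values had an SD of 1.37 for Cdk7 and 1.75 for Trrap on the log2 scale. The rest of the 20 genes with the smallest p (10 per direction) were Stk3, Itpk1, Stk40, Dguok, Prkab2 and Limk2 on the lower side, from -0.85 to -0.64, and Map2k4, Fgfrl1, Lck, Cpne3 and Mink1 on the higher side, from 0.63 to 1.36.

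Of the 713 genes, 112 had an unadjusted p under 0.05, 45 lower and 67 higher. DESeq2 called 6 genes (Cdk7, Fgfrl1, Mark4, Nme1, Ret and Riok3) and limma with sample weights estimated per group called 1 (Ret). Of the 2919 sgRNAs tested, 0 passed by edgeR, 418 had an unadjusted p under 0.05, and DESeq2 called 110 and limma 0. Non-targeting controls were higher here too, with a median of 0.26 and 66 of 97 higher, and scaling to them shifted the median over genes by -0.14 and left 0 gene calls by edgeR. In simulated counts for this comparison the test recovered 70% of genes changed 2-fold and 97% of those changed 4-fold, over 713 genes, but only 2% and 36% of sgRNAs so changed. The gene shares hold for many genes changed at once and equal changes in all sgRNAs of a gene. They do not exclude 2-fold differences between the tumour groups. Leaving out immunocompetent replicate 2 gave 20 gene calls, Ret, Nme1, Jak2, Riok3, Ern1 and Map2k4 among them, and leaving out replicate 1 gave 1 (Ret).

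Among single sgRNAs, a Sgk1 sgRNA (ATATTCTCCTAGACTCCCAG) was at -3.34 ± 0.52 and an Erbb4 sgRNA (TTGCTGATCCTCAAACAACA) at -2.22 ± 0.45, both with an adjusted p of 0.268. A Chek1 sgRNA (TACAACAAACCACTTAACAG) had 1 count over the immunocompetent libraries and 731 over the nude-mouse libraries, a ratio of 517 after scaling to the totals (95% counting interval 92.5 to 20455). The 3 sgRNAs with the smallest p on the higher side were a non-targeting control (ACCCAGATTCGCATTCGGAT) at 1.91 ± 0.37, a Map3k3 sgRNA (ACAGACACATGGTAGCGCCT) at 1.76 ± 0.37 and a Dtymk sgRNA (TGGTGTAAACAACCGGACGT) with 558 against 4 counts. The Dtymk sgRNA varied widely among immunocompetent libraries, with a mean of 75.1 CPM and an SD of 95.9 after TMM scaling.

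No gene list passed in this comparison by camera, with a preset or an estimated correlation, or by fry, and 1 list had an unadjusted camera p under 0.05. That list was the JAK kinases, which signal from interferon and other cytokine receptors: its 4 members were at -1.19 ± 0.37 (Jak2), -0.50 ± 0.20 (Jak3), -0.33 ± 0.24 (Tyk2) and -0.31 ± 0.45 (Jak1). The camera test gave an adjusted p of 0.125 (adjusted p = 0.993 with an estimated correlation), and an adjusted p of 0.0123 without immunocompetent replicate 2. Without any other single library the list did not pass: the adjusted p was 0.511 and 0.458 without immunocompetent replicates 1 and 3, and 0.0587, 0.153 and 0.246 without nude replicates 1, 2 and 3. Over all genes 0 members of any list were called. Adjusted over the list alone, 1 of the 4 JAK kinases was called lower, 1 of 7 transcriptional CDKs higher, 1 of 52 receptor tyrosine kinases higher, and 3 of 25 members of the Hippo and LKB1-AMPK list lower and 1 higher, with 0 in the other 16 lists. The test and the median or mean of the list differed in sign for cell cycle and mitosis, transcriptional CDKs, NF-kB and TNF, SRC and focal adhesion, TGF-beta and BMP, Hippo and LKB1-AMPK, and casein and dual-specificity kinases.

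Cdk10, the cyclin-dependent kinase named in the title of the series, had its lowest counts in immunocompetent tumours, with a wide spread. Summed over its 4 sgRNAs it had 43, 737 and 1772 counts in immunocompetent replicates 1, 2 and 3, which were 14.9, 202 and 483 CPM. Nude-mouse tumours held 516 to 649 CPM and culture 486 to 542 CPM. The gene's log2 fold change, immunocompetent against nude-mouse tumours, was -1.27 ± 0.83 (adjusted p = 0.457), with 4 of 4 sgRNAs lower. It was 0.20 ± 0.13 in nude-mouse tumours against culture (adjusted p = 0.240) and -1.06 ± 0.93 in immunocompetent tumours against culture (adjusted p = 0.525).

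By sgRNA, immunocompetent against nude-mouse tumours, TATGCCAACACCCTTCTCGG was at -2.03 ± 0.83 (adjusted p = 0.308), TCTCCGCCATCCAAACATTG at -3.47 ± 1.73 with 0, 18 and 0 counts in the immunocompetent libraries, ACAGGAACTTCATCATCCAC at -0.60 ± 0.75 and GACAAGGGCTGTGTAAAGAC at -0.35 ± 1.28. In nude-mouse tumours against culture, ACAGGAACTTCATCATCCAC fell by 0.84 (adjusted p = 0.0361) and TATGCCAACACCCTTCTCGG rose by 0.73 (adjusted p = 0.0407). The first missed the threshold without culture replicate 1, 2 or 3 (adjusted p = 0.145, 0.0714 and 0.160) or nude replicate 2 (0.0752), and the second without these (0.138, 0.128, 0.0983 and 0.0901), without nude replicate 1 (0.0603) or with control scaling (0.126). Across the alternatives the gene's difference between tumour groups ran from -2.39 to -0.57, with adjusted p from 0.165 to 0.804. It was -0.72 without immunocompetent replicate 1 and -2.39 without replicate 3, and the GACAAGGGCTGTGTAAAGAC sgRNA turned to 0.22 and 0.09 without replicates 1 and 2.

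**Figure D2:**
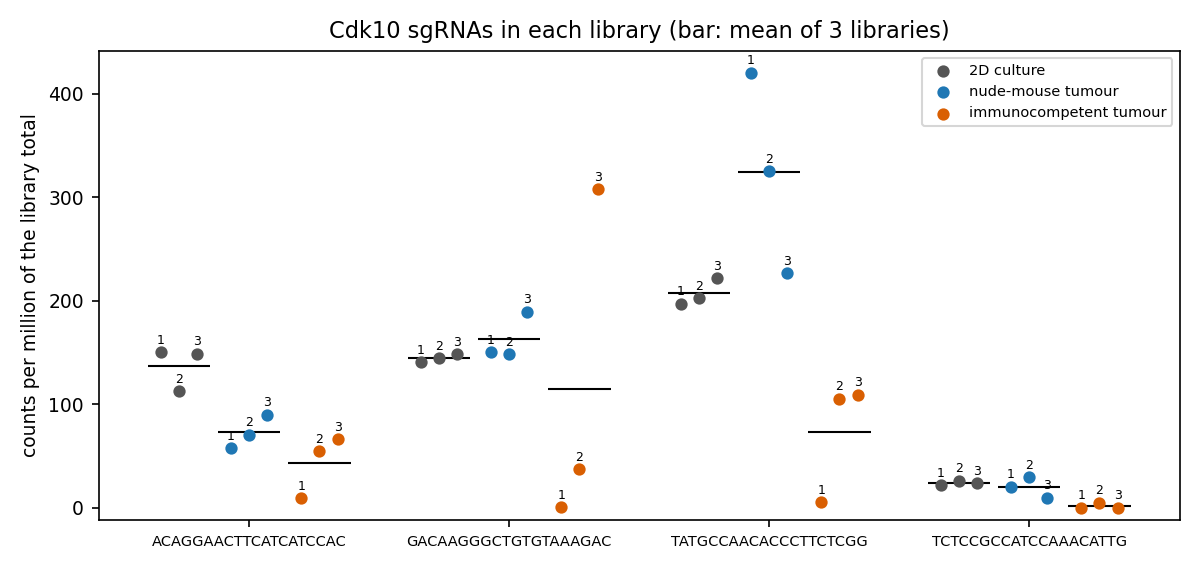
CPM (counts scaled to equal library totals) for each of the 4 Cdk10 sgRNAs in the 9 libraries, with the replicate number above each point and a bar at the mean of 3 libraries. Immunocompetent replicate 1 held 43 Cdk10 counts in all, and replicates 2 and 3 held 737 and 1772.

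The comparison of nude-mouse tumours with culture asks which knockouts are lost or gained during growth as a tumour without T cells. Of 713 genes, 143 were called lower and 136 higher in sgRNA abundance. Single non-targeting controls were called about as often as sgRNAs in general, as given below, so not every gene call need be a knockout effect. Vrk1, a nuclear kinase active in mitosis and nuclear envelope assembly, had the largest drop, and fell by 4.03 ± 0.20 on the log2 scale (adjusted p = 7.80e-07, n = 3 and 3). Riok1, which acts in maturation of the small ribosomal subunit, fell by 3.86 ± 0.28, and Actr2, a subunit of the actin-nucleating ARP complex, fell by 3.58 ± 0.15. Taok1, a kinase upstream of MAP kinases and of the Hippo pathway, rose most, by 2.01 ± 0.07 (adjusted p = 1.68e-07), and Dgkd, a diacylglycerol kinase, rose by 1.63 ± 0.10. All 4 sgRNAs of each of these 5 genes went the same way.

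The RAF-MEK-ERK list fell as a group, with 9 of 16 members called lower and 2 higher, over all genes and equally when adjusted over the list alone (camera adjusted p = 3.86e-06, adjusted p = 0.0979 with an estimated correlation). Among the 9 were Map2k1 (MEK1) at -2.18 ± 0.10, Map2k5 (MEK5) at -1.95 ± 0.12 and Mapk7 (ERK5) at -3.34 ± 0.24. In the JNK and p38 list, which had 3 members called lower and 6 higher, Map3k2 (MEKK2) fell by 1.58 ± 0.23 and Map3k3 (MEKK3) fell by 1.41 ± 0.20. One Mapk7 sgRNA (TTCCCTGCACGAGTATACGC) fell by 4.31 ± 0.30, from 2364 to 125 counts over 3 libraries.

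Kinases that most cells need fell as well. Of 25 pan-essential kinases 17 were called lower and 1 higher (camera adjusted p = 0.000145, adjusted p = 0.199 with an estimated correlation), among them Pkmyt1, which restrains CDK1, at -2.44 ± 0.23, Cdc7, which fires replication origins, at -1.74 ± 0.17, and Pik3r4, a subunit of the VPS34 complex, at -1.31 ± 0.13. Of 26 cell cycle and mitosis kinases 13 were called lower and 5 higher (camera adjusted p = 0.0110, adjusted p = 0.525 with an estimated correlation), with Cdk6 at -0.73 ± 0.08. Adjusted over the list alone these counts were the same. Other genes that fell were Csnk1a1 (casein kinase 1 alpha, which marks beta-catenin for breakdown), Oxsr1 and the glycolytic enzyme Pgk1, from -2.99 to -2.47.

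The Hippo and LKB1-AMPK list shifted upwards, with 8 of 25 members called higher and 2 lower, and equally when adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.482 with an estimated correlation). Taok1 rose as above, and Mark2 (0.80 ± 0.10) and Nuak2 (0.46 ± 0.07), kinases that LKB1 activates, rose, while Stk3 (MST2, a core Hippo kinase) fell by 0.52 ± 0.06. The median of this list was 0.10, but -0.11 against the non-targeting controls, and the list missed the threshold without culture replicate 3 (adjusted p = 0.0620), nude replicate 1 (0.131) or nude replicate 2 (0.0694). Other genes that rose were Stk25 (1.36 ± 0.12), Stk24 (0.90 ± 0.08), Sgk1 (1.20 ± 0.10), the tyrosine kinases Abl1 (1.12 ± 0.12) and Fer (0.96 ± 0.07), and Bmpr2, a BMP receptor (0.82 ± 0.07). Tpr and Clp1 were called higher at 0.85 and 0.82, with 2 and 3 sgRNAs higher. Tpr missed the threshold without culture replicate 1, 2 or 3 (adjusted p = 0.0567, 0.0501 and 0.0644), and Clp1 turned to -0.22 without its most abundant sgRNA.

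The remaining 16 lists did not pass the camera test. Counts called lower and higher were 4 and 1 of 7 transcriptional CDKs, 6 and 3 of 12 DNA damage kinases, 8 and 3 of 21 PI3K-AKT-mTOR members, 3 and 6 of 22 JNK and p38 members, 2 and 1 of 4 JAK kinases, and 5 and 1 of 19 kinases of nucleic acid sensing. They were 5 and 3 of 16 NF-kB and TNF members, 0 and 1 of 3 integrated stress response kinases, 4 and 10 of 52 receptor tyrosine kinases, 3 and 3 of 14 SRC and focal adhesion kinases, and 1 and 3 of 12 TGF-beta and BMP receptors. They were 2 and 0 of 9 autophagy kinases, 4 and 8 of 34 metabolic kinases, 6 and 4 of 24 casein and dual-specificity kinases, 2 and 6 of 21 leukocyte-restricted kinases, and 2 and 4 of 23 kinases of retina, muscle and germline. Adjusted over the list alone the counts differed for DNA damage (6 and 4), PI3K-AKT-mTOR (9 and 3), nucleic acid sensing (4 and 0), NF-kB and TNF (5 and 4), metabolic (4 and 7) and casein and dual-specificity kinases (7 and 4). Camera adjusted p in these lists ran from 0.426 to 0.757. The JNK and p38 list had a negative median and mean and an upward test, and the SRC and focal adhesion list a negative mean with a positive median and an upward test. Jak1 fell by 1.79 ± 0.20 and Jak2 fell by 0.28 ± 0.08, while Jak3 rose by 0.30 ± 0.09. Without culture replicate 1 or 3 the adjusted p was 0.109 and 0.118 for Jak2 and 0.0860 and 0.0753 for Jak3, without culture replicate 2 it was 0.0838 for Jak3, and without nude replicate 2 it was 0.0591 for Jak2. Jak2 was at 0.058 without its most abundant sgRNA.

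By sgRNA, 831 of 2936 passed (28.3%), 404 lower and 427 higher. Of the 97 non-targeting controls tested, 24 were called higher and 5 lower, a share much like that over all sgRNAs. A call for a single sgRNA therefore does not by itself show an effect of the knockout. The gene test left the controls out, so how often it would call sets of sgRNAs without a knockout is not known. The controls lay above targeting sgRNAs, with a median log2 fold change of 0.21 and 71 of 97 higher (camera p = 0.00115, and p = 0.0107 with an estimated correlation). Scaled to the controls, the median over genes shifted by -0.19 and the calls became 311 lower and 36 higher, so the share of genes called higher depends on the scaling. Without culture replicate 1, 2 or 3 the gene calls were 164, 178 and 159 and the sgRNA calls 390, 396 and 393. Fitting all 9 libraries together gave 51 gene calls, and rank aggregation over sgRNAs 38.

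The comparison of immunocompetent tumours with culture asks the same of growth in hosts with T cells. Of 713 genes, 27 fell and 8 rose. Vrk1 again had the largest drop, and fell by 4.57 ± 0.31 (adjusted p = 0.000671, n = 3 and 3). Mapk7 was at -4.09 ± 0.64, Csnk1a1 at -3.62 ± 0.45, Pgk1 at -3.00 ± 0.32 and Map3k2 at -2.79 ± 0.39, each with 4 of 4 sgRNAs lower. Actr2 was at -2.59 ± 0.39, Pkmyt1 at -2.15 ± 0.30 and Map2k5 at -2.15 ± 0.20, all called. Taok1 rose by 2.87 ± 0.53, Stk25 by 1.38 ± 0.29, Stk24 by 1.05 ± 0.17, and the splicing-factor kinases Clk2 and Clk3 by 0.93 ± 0.19 and 0.74 ± 0.16. Ret (1.28 ± 0.26), Nme1 (1.00 ± 0.19) and Chek2, a DNA damage checkpoint kinase (1.29 ± 0.28), rose too, with adjusted p of 0.0422, 0.0322 and 0.0473. Chek2 was at -0.012 without its most abundant sgRNA, and Prkag2 (0.53 ± 0.13) and Ksr1 (0.57 ± 0.14) did not pass.

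In the RAF-MEK-ERK list 5 of 16 members were called lower and 0 higher, and 7 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00216, adjusted p = 0.357 with an estimated correlation). The pan-essential list had 2 of 25 called lower, Pkmyt1 and Pik3r4 (-1.16 ± 0.25), and 7 adjusted over the list alone, while Aurka was at -1.89 ± 0.43 and Riok1 at -2.21 ± 0.56 without passing over all genes. The cell cycle and mitosis list had 2 of 26 called lower, Vrk1 and Pkmyt1, and 3 adjusted over the list alone. Both lists had a camera adjusted p of 0.00216, and 0.251 with an estimated correlation. Of the 4 JAK kinases, Jak1 fell by 2.08 ± 0.34 and Jak2 was at -1.45 ± 0.37, with 1 called lower and 2 adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.568 with an estimated correlation). Without immunocompetent replicate 2 or 3 the RAF-MEK-ERK list missed the threshold (adjusted p = 0.0905 and 0.0530), and without replicate 1 or 3 the JAK list did (0.199 and 0.0877).

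The other 16 lists did not pass (camera adjusted p from 0.308 to 0.878). Among them the nucleic acid sensing and innate signalling list had 2 of 19 members called lower and 0 higher, and the Hippo and LKB1-AMPK list had Stk3 (-1.28 ± 0.16) and Stk11 (-1.32 ± 0.27) called lower and Taok1 higher. Adjusted over the list alone the counts of these 16 lists were those over all genes except for PI3K-AKT-mTOR (2 lower, against 1), TGF-beta and BMP receptors (1 lower and 1 higher, against 1 lower) and receptor tyrosine kinases (0, against 1 higher). The mean and median of the casein and dual-specificity list differed in sign. By sgRNA, 9 of 2934 passed, 8 lower and 1 higher, where in simulated counts the test recovered 0% of sgRNAs changed 2-fold and 1% of those changed 4-fold. The higher one was a Stk24 sgRNA (GCAGTCAGCCTACGACTCAA) at 1.92 ± 0.24, and a Map2k5 sgRNA (GATTCCAAATAGTGGCGCGG) fell by 3.15 ± 0.31. A Map3k2 sgRNA (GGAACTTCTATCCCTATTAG) had 1 count over the 3 immunocompetent libraries and 2823 over culture, a ratio of 2061 (95% counting interval 370 to 81419), and the Mapk7 sgRNA TTCCCTGCACGAGTATACGC had 1 against 2364, a ratio of 1726 (309 to 68186).

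Non-targeting controls were higher here too, with a median of 0.49 and 77 of 97 higher (camera p = 3.69e-06, and p = 0.00299 with an estimated correlation), and scaled to them the median over genes shifted by -0.33 and the calls were 69 lower and 2 higher. Of the 35 gene calls, 3 remained without culture replicate 1 (Lamtor3, Map2k5 and Vrk1), 11 without replicate 2 and 3 without replicate 3, while 122 genes were called without immunocompetent replicate 1 and 119 without replicate 2. By edgeR the sgRNA calls were 0 without culture replicate 1, 2 or 3 (238, 242 and 231 at an unadjusted p under 0.05), and 313, 288 and 26 without immunocompetent replicates 1, 2 and 3. DESeq2 called 101 genes and limma 69, and without the most abundant sgRNA of each gene 13 were called.

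The genes called in both tumour groups against culture were largely those named above: 26 were lower and 6 higher in both, and 0 went opposite ways. The 26 included Vrk1, Mapk7, Csnk1a1, Map2k5, Map3k2, Jak1, Pgk1 and Stk3, and the 6 were Taok1, Stk25, Stk24, Clk2, Clk3 and Chek2. Scaled to the controls, 2 of the 6 (Taok1 and Stk25) were called higher in both, and without culture replicate 1, 2 or 3 the higher calls in immunocompetent tumours were 0. Independent lists of these sizes would share 5.42 lower and 1.53 higher genes. Simulated unchanged tumour groups against the same culture libraries shared 0, but with a mean of 0.04 and 0 calls per simulation by edgeR they had almost none to share, so that count gives no level for the overlap of these lists. Of the 713 genes, 61.6% changed in the same direction in both tumour groups, against a simulated mean of 51.0% and a simulated highest of 56.9%. Agreement in direction was therefore not general over the genes. Across the 713 genes, which are not independent replicates, the log2 fold changes correlated at 0.702 (simulated 0.0323), with a covariance of 0.276 against a simulated 0.00107. The highest simulated covariance was 0.0050, which argues against the measured spread among the shared culture libraries as the main source of this correlation. A deviation common to all 3 culture libraries is not covered by the simulation. These libraries could not be split with 2 in each part, so part of the excess overlap may still come from sharing them. Called against culture in immunocompetent tumours but not in nude-mouse tumours were Ret, Nme1 and Stk11, and for these the direct comparison of the tumour groups gave adjusted p of 0.185, 0.245 and 0.245, so that difference did not pass.

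**Figure D3:**
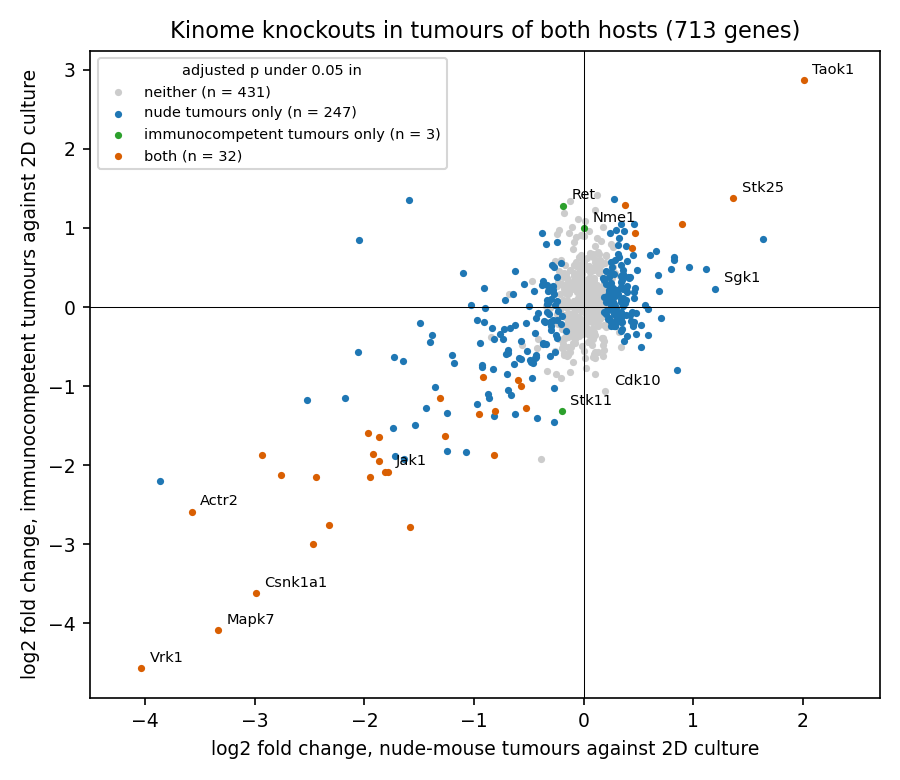
Log2 fold change of each of 713 genes in nude-mouse tumours (horizontal axis) and in immunocompetent tumours (vertical axis), each against the same 3 culture libraries, coloured by where the adjusted p was under 0.05. The 32 genes called in both groups lie in the lower left (26) and upper right (6).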

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

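Leaving out libraries in the list tests was chosen after the data were seen, and all other alternatives before. Of the values of named genes under alternatives that kept all libraries, 327 for immunocompetent against nude tumours kept direction and side of the threshold and 9 gained a call. For nude tumours against culture 987 kept both, 130 lost the call and 8 gained it, and for immunocompetent tumours against culture 356 kept both, 41 lost it and 31 gained it. Causes were not tested except where a setting uses fewer samples or sgRNAs.

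Gene calls between tumour groups (0) became 6 with DESeq2, 1 with limma, 1 in a fit of all 9 libraries and 2 with the mean of sgRNA log2 values, and ran from 0 to 20 with a library left out. sgRNA calls (0) became 110 with DESeq2 and 35 with all 9 libraries, and stayed at 0 with any library left out. In nude tumours against culture, gene calls (279) became 51 with all 9 libraries and 38 with rank aggregation, and 159 to 319 with a library left out, and sgRNA calls (831) became 26 with all 9 libraries and 390 to 1108 with a library left out. In immunocompetent tumours against culture, gene calls (35) became 71 with control scaling, 101 with DESeq2, 69 with limma, 76 with all 9 libraries, 79 with the mean of sgRNA log2 values, 66 with fry and 13 without the most abundant sgRNA, and 3 to 122 with a library left out. There sgRNA calls (9) became 46 with control scaling, 343 with DESeq2, 37 with limma, 124 with all 9 libraries, 14 without the robust step, and 0 to 313 with a library left out.

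The replicate block moved gene calls to 0, 268 and 66 and sgRNA calls to 0, 760 and 12 for immunocompetent against nude tumours, nude tumours against culture and immunocompetent tumours against culture. Deviations of libraries with the same number correlated between -0.0206 and 0.0462, so the numbers were not taken to pair samples.

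The lists past the threshold (0, 4 and 4) became 0, 0 and 0 with an estimated correlation, and 0, 16 and 7 with fry, which asks whether a list moves one way and not whether it differs from other genes. With a library left out they were 0 to 1, 3 to 4 and 2 to 4. Shared calls (32) became 72 with DESeq2. At a minimum of 10 counts, sgRNAs detected became 2934 in culture and 2862 in immunocompetent tumours. The top 5% of sgRNAs held 11.5%, 14.4% and 19.5% of counts in culture, nude and immunocompetent tumours.

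These values changed sign. In nude tumours against culture, Cdk10 was -0.034 with the mean of sgRNA log2 values, -0.014 with fry and -0.17 without the most abundant sgRNA. Eif2ak2 was 0.0054 with that mean, 0.016 with fry and from -0.13 to 0.084 with a library left out. Without the most abundant sgRNA, Clp1 was -0.22, Jak2 0.058, Tyk2 0.063 and Camkv -0.059, and with a library left out Tyk2 ran from -0.14 to 0.027. In immunocompetent tumours against culture, Jak3 was 0.0046 with the mean of sgRNA log2 values, 0.16 with rank aggregation, 0.066 with fry and 0.19 without the most abundant sgRNA, where Chek2 was -0.012 and Tyk2 0.11. With a library left out, the Cdk10 sgRNA GACAAGGGCTGTGTAAAGAC in immunocompetent tumours ran from -3.05 to 0.22 against nude tumours and from -2.80 to 0.48 against culture, and TCTCCGCCATCCAAACATTG from -0.57 to 0.16 in nude tumours against culture.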

Other observations

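The tests of the spread among immunocompetent tumours, of the cost of a targeted cut and of abundance in culture were chosen only after the result was seen. Intervals of ratios and of differences of medians come from 1000 bootstrap draws over sgRNAs, and those of control terms from a linear model over sgRNAs, so they do not cover the spread between libraries.

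In nude-mouse tumours against culture, genes of lists that did not pass the camera test fell or rose. Ptk2 (focal adhesion kinase) fell by 2.06 ± 0.19 and Ilk (integrin-linked kinase) fell by 1.44 ± 0.11, while Fer and Abl1 of the same list rose. Pkm, which makes pyruvate in glycolysis, fell by 1.20 ± 0.14 and Hk2, a hexokinase, fell by 0.72 ± 0.12, in a metabolic list with 4 members called lower and 8 higher. In NF-kB signalling, Map3k7 (TAK1) was at -1.27 ± 0.11, Chuk (IKK alpha) at -0.92 ± 0.09 and Map3k14 (NIK) at -0.91 ± 0.12, all called, in a list with 5 members called lower and 3 higher. Pdpk1, which activates AKT, fell by 0.97 ± 0.10 and Pik3ca fell by 0.70 ± 0.08, while Sgk1 rose. Among receptors Ephb2 rose by 0.69 ± 0.08 and Tie1 by 0.59 ± 0.08, and Erbb3 fell by 0.44 ± 0.08.

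Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes the real split gave 0 calls between tumour groups (highest other split 0), 279 in nude tumours against culture (0) and 35 in immunocompetent tumours against culture (0), and for sgRNAs 0 (0), 831 (0) and 9 (0). As many calls as the real split came from 10 of 10 splits between tumour groups, for genes and sgRNAs alike, and from 1 of 10 in each comparison with culture. Between tumour groups the real count of 0 fixed this outcome. Against culture every other split mixes tumour and culture libraries, which widens the spread within its groups. These counts therefore draw no line between a group effect and chance.

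Counts varied more among immunocompetent than among nude-mouse tumours. Counting noise of the reads is argued against as the whole cause, since with that noise subtracted the coefficient of variation of control sgRNAs was 2.34 times as high (95% interval 2.00 to 2.76; 1.79 without immunocompetent replicate 1), a measure on which thinning to 1 total (2.36) had little to act and so tested nothing further. Random loss and expansion of cells whatever their sgRNA, or of DNA templates in PCR, may account for part of it, because these controls carry no knockout. Whether knockout-specific selection added to the difference between hosts could not be told from these values. Targeting sgRNAs were 1.32 times as variable as controls (1.20 to 1.47) in immunocompetent tumours and 1.45 times (1.28 to 1.66) in nude-mouse tumours. The ratio of these was 0.909 (0.760 to 1.06). Spread shared by all sgRNAs pulls such ratios towards 1, so a rise in selection could be hidden. The coefficients were 0.607 for targeting and 0.461 for control sgRNAs in immunocompetent tumours, and 0.285 and 0.197 in nude-mouse tumours. How far selection differed from tumour to tumour stays open. The immune state of the host was not tested apart from these.

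Targeting sgRNAs lay below non-targeting controls in tumours. A cost of any targeted cut may contribute: sgRNAs of retina, muscle and germline kinases, with little expected role in these cells, were 0.16 below controls in nude-mouse tumours against culture (difference -0.162, 95% interval -0.286 to -0.0361), while in immunocompetent tumours against culture the interval of the difference held 0 (-0.197, -0.333 to 0.0301). GC content is argued against as the main cause, since the control term stayed at 0.303 (0.125 to 0.480) with it as a covariate, beside 0.319 without. In culture the controls already lay 0.490 (0.217 to 0.646) above other targeting sgRNAs on the log2 scale. With abundance in culture as a covariate the control term was 0.225 (0.0507 to 0.399). It stayed above 0, which argues against abundance in culture as the whole cause, but the interval is too wide to give its share. With mean abundance over both groups it was 0.0797 (-0.0784 to 0.238), but that covariate holds the tumour counts themselves, so the part played by abundance stays open.

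RAF-MEK-ERK sgRNAs were lower in both tumour groups. Of the 9 members called lower in nude-mouse tumours, 8 stayed called without the most abundant sgRNA. That test leaves out the sgRNA with the highest counts and not the one that fell most. It therefore cannot settle whether a single sgRNA per gene carried the calls. Of the 279 genes called in nude-mouse tumours against culture, 148 had all their sgRNAs going the same way. All 279 had at least 2 going the same way, but sgRNAs without an effect would often meet that bar by chance. The count for at least 2 therefore does not settle the question either. Both counts are over all called genes and not over the 9 members. In culture the median of the list's sgRNAs lay 0.0503 above other targeting sgRNAs on the log2 scale (95% interval -0.172 to 0.233), where pan-essential kinases lay at -1.67. The list as a whole was thus not low in culture as pan-essential kinases were. No library from before culture was available, so abundance in culture mixes starting abundance with loss. The median also pools members that fell with members that did not. Loss already under way in culture for the 9 that fell stays open. Growth as a tumour rather than in culture, the difference that the design names, was not tested apart from a difference in time or cell divisions, as the harvest time of the cultures is not given in the sources used here. The list call did not hold with an estimated correlation.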
